A study of Mus musculus with 8 samples.

How the data were processed

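The 8 libraries were read from 1 table of FPKM as deposited by the authors, with 1 column per library and 45777 NCBI gene identifiers. Of these 45679 were matched to gene symbols of the mouse assembly GRCm38.p6 (mm10) and 98 were not. Per the labels, total RNA was isolated with TRIzol and an RNeasy Plus kit, and libraries were made with a TruSeq Stranded Total RNA Gold kit. The submitters' processing notes name Trimmomatic 0.38, HISAT2, StringTie and mm10. The role and order of these tools, the versions of HISAT2 and StringTie, the read depth, and whether RNA of several animals was pooled are not given in the sources used here. Groups and tissues were taken from the sample titles. No library was left out.

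Values were taken as log2(FPKM + 1), which understates ratios of genes near or below 1 FPKM. A gene was kept in a tissue when it reached 1 FPKM in at least 1 of its 4 libraries, which left 12866 genes in liver and 15245 in colon. Ratios were NASH over control, each EV dose over NASH, and EV high dose over EV low dose, and genes were counted as apart at 2-fold or more. With 1 library per group no test on genes was run and no probability is given.

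The 54 gene lists, 40 used in liver and 41 in colon, the thresholds, the rule for naming genes and most alternatives were fixed before the data were examined. A list was tested when 5 or more of its members were kept, which held for 38 lists in each tissue. The median log2 ratio of its members was ranked among 10000 random lists of the same size drawn from the same of 20 expression bins, and a list was called high or low in the outer 2.5% on either side, where 1.9 of 38 lists are expected by chance. Genes act together, so these ranks are a description of these libraries. The size given for a list is its median less the median of its random lists. That form was chosen after a trend of the ratios with expression was seen, and it leaves the ranks as they were.

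The median gene of liver lay off 0 in each of the 3 main ratios, so liver gene ratios and member counts are given relative to the median gene, a choice made after that shift was seen. Genes were named when they held 1 of the 8 largest or 8 smallest ratios with 5 FPKM or more in the higher library. Predicted genes, receptor segments, small RNAs and mitochondrial genes were left out of that ranking by biotype and name prefix. Up to 4 members with the largest ratios were also named for each called list and for lists that name an aim of the study. Further genes named with FPKM alone, among them Muc2, Reg3b, Hamp, Hoxb13, Ucp1, Mmp7, Reg4, Sult2a8 and Inmt, were chosen after their values were seen. Symbols of mitochondrial genes were matched by their bare names after the prefixed names found none. Members of near-identical families such as Mup, Hamp and Hamp2, amylase and ribosomal pseudogenes cannot be told apart with certainty in such a table.

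The position of an EV library was the median over genes 2-fold apart between NASH and control of the share of that difference left, with a 95% interval over genes. The same position was read on genes chosen from the other EV library against control. The share, and the sharing of genes between doses, were set beside 100 simulated sets of libraries with no group differences that share a NASH library, with noise drawn from the difference between the 2 EV libraries, and beside the number for independent lists.

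Alternatives were a pseudocount of 0.1 or 5 FPKM, median-of-ratios scaling, scaling of each library to the same sum, no filter, a filter at 5 FPKM, the mean over members, leaving out predicted, small RNA and receptor segment genes, and EV libraries against control. Added after the data were seen were protein-coding genes only, the position of the EV libraries relative to the median gene, and leaving out genes with over 75% of a tissue's summed FPKM in 1 library. A first version of the latter was defined over both tissues together. Lists of anterior and posterior Hox genes were written before their values were seen, and a list of seminal vesicle and prostate genes after the first of its values were seen. Leaving out a replicate was not possible.

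The code was tested on simulated libraries with known differences. Genes set 4-fold apart passed 2-fold in 100% of cases, 1.5-fold genes in 2% (liver noise) and 8% (colon noise), and unchanged genes in 0.332% and 1.49%. Random lists without a shift were called in 4% and 5.5% of cases and lists shifted by 0.5 in 100%. A true share left of 0.7 was read as 0.698 and 0.695, and a true step of -0.6 as -0.59 and -0.53, so the step in colon is read somewhat small. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.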

Results

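RNA of mouse liver and colon was compared between control animals, animals with non-alcoholic steatohepatitis (NASH), and NASH animals given a low or a high dose of extracellular vesicles (EVs) from bovine colostrum. The 8 libraries held 1 library per group and tissue. With no replicates, each comparison describes 2 libraries, carries no error, and cannot say how far animals of the same group differ. The labels gave no dose amounts, sex, strain, diet or time of treatment, and that the EV groups had NASH was taken from the design text of the series. Genes apart in the control libraries, given at the end, leave open a difference in alleles or time of collection between control and the other groups. NASH over control and each step toward control would hold such a difference too. Values were FPKM (fragments per kilobase of transcript, scaled by the mapped reads), so the sequencing depth was unknown. Between 10469 and 12420 genes reached 1 FPKM in the liver libraries and between 13863 and 14480 in the colon libraries. The Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y were present at 3.04 FPKM or more in each of the 8 libraries, while Xist, the RNA that coats the inactive X chromosome of females, stayed at 0.0185 FPKM or less. Hoxb13, a homeobox gene of the hindgut, was at 134 FPKM in the colon control library and listed at 0 in the liver control library. The small RNA genes Rn7s1, Rn7s2, Rn7sk, Rpph1 and Rmrp held 49.7% of the summed FPKM of the liver NASH library and 54.9% of the liver control library.

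In liver the median gene was 0.55 log2 units higher in the NASH library than in the control library, and stood at -0.14 in EV low dose and -0.13 in EV high dose against NASH. Log2 ratios of liver genes are therefore given relative to the median gene, and liver list members are counted relative to all genes, while FPKM are as deposited. Member counts depend on this choice: as deposited, more members count as higher and fewer as lower in the NASH liver. Kupffer cell markers, for example, had 9 of 11 higher as deposited and 6 relative to all genes. Complement and coagulation had 4 of 25 lower as deposited and 14 relative to all genes. In colon the median gene stood between -0.06 and 0.08 and genes are given as deposited. For gene lists, the value given is the median log2 ratio of the members relative to random lists of matched expression. In brackets, the number after a list is this value and the number after a gene name is its log2 ratio.

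The NASH liver held far more RNA for acute phase proteins, macrophages, matrix and lipid droplets than the control liver, and far less RNA for male-biased secreted and metabolic proteins. Lcn2, which encodes the iron-carrier-binding protein lipocalin-2, was at 633 FPKM against 1.80 in the control library, a log2 ratio of 7.27 (gene ID 16819, chromosome 2, 32384637 to 32387739). Cidec, a protein of large lipid droplets, was at 55.1 against 0.0793 FPKM (log2 5.15), Mmp12, the macrophage elastase, at 30.1 against 0.0526 (log2 4.33), and Cd63, a tetraspanin of lysosomes and vesicles, at 52.2 against 0.987 (log2 4.19). Apoa4, a lipoprotein component, was at 3027 against 44.5 FPKM (log2 5.50), Ly6d at 170 against 0.558 (log2 6.22) and the female-biased Cyp2a4 at 104 against 2.28 (log2 4.45). In the other direction, Mup7, a major urinary protein that carries pheromones, was at 20.4 FPKM against 6924 in the control library (log2 -8.89, gene ID 100041658, chromosome 4, 60066469 to 60070475), and Hsd3b5, a male-biased steroid dehydrogenase, at 0.160 against 182 (log2 -7.86).

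Male-biased liver genes were lower in the NASH library in 20 of 20 members, with a list median of -3.63. Mup1 stood at -7.38 and Slco1a1, an uptake carrier for organic anions, at -6.34 (158 against 1.86 FPKM). Outside the list, Mup14 stood at -7.18 and Cyp2c54 at -5.96. Mup genes made up 13.8% of the protein-coding FPKM in the control liver and 1.11% in the NASH liver. They are near-identical copies, so how the FPKM divide among them is uncertain. Female-biased genes lay the other way, with a median of 1.39, 6 members higher (Cyp2a4 and Cyp2b9, the latter at 2.48) and 2 lower of 10. Cytochrome P450 genes had 12 members lower, 4 higher and 4 within 2-fold of 20 (median -0.97), with Cyp2c54 and Cyp2c29 (log2 -4.99) lowest. Bile acid synthesis and transport had 9 lower and 4 higher of 19 (median -0.65). Its members split: Cyp8b1 (141 against 22.2 FPKM in NASH, log2 -3.17) and Cyp7b1 (log2 -3.58) were lower, and Cyp7a1, which encodes the first enzyme of the classical pathway, was higher (57.8 FPKM in NASH against 9.52, log2 1.93).

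Genes of secreted and nitrogen-handling hepatocyte proteins were lower as well. Hepatocyte identity genes had 10 of 19 members lower (median -0.77, with Apoa2 at -2.29 and Ttr at -2.23). Complement and coagulation had 14 of 25 lower, or 4 as deposited (median -0.54, with C8g at -2.12 and C8a at -2.02). Urea cycle and amino acid metabolism had 11 of 21 lower (median -0.52, with Gnmt at -3.19 and Hal at -2.79). Cholesterol synthesis was lower in 16 of 20 members with none higher (median -1.65), among them Fdps (113 FPKM in control, 17.4 in NASH, log2 -3.18), Idi1 (log2 -3.10) and Sqle (log2 -2.55). De novo lipogenesis had 6 lower and 2 higher of 17 (median -0.62): Thrsp, a nuclear protein that raises lipogenic enzymes, stood at -2.66 and Acss2 at -2.60, against Scd2 at 1.31 and Fads2 at 1.21. Transcripts encoded by mitochondrial DNA were lower in 8 of 13 (median -0.68, with COX3 at -1.45), and the erythroid markers in 5 of 5 (median -0.86, with Alas2 at -2.37).

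Lipid handling outside synthesis was higher in the NASH liver. Lipid droplet and uptake genes had 7 higher and 1 lower of 14 (median 0.98), with the fatty acid receptor Cd36 at 131 against 7.68 FPKM (log2 3.38), Plin4 at 2.58 and Pparg at 1.35. Fatty acid oxidation and PPARA targets had 9 of 25 higher and none lower (median 0.82): Fgf21, a fasting hormone of the liver, at 32.1 against 0.641 FPKM (log2 3.78), Acot2 at 2.86, Cyp4a31 at 1.96 and Vnn1 at 1.77. The NRF2 and antioxidant list (median 0.63, 5 higher and 2 lower of 17) was led by Gsta1 (log2 3.94), Srxn1 (log2 2.46) and Hmox1 (log2 2.04).

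Myeloid and matrix lists were higher in the NASH liver. Lipid-associated macrophage markers had the highest list median, 2.48, with 10 of 12 members higher, among them Gpnmb (26.3 against 0.0243 FPKM, log2 4.18) and Lgals3 (log2 3.76). MHC class II was higher in 7 of 7 (median 1.88, with Cd74 at 1.97) and macrophage markers in 12 of 14 (median 1.72, with Lyz2 at 2.31 and Cd68 at 2.16). Kupffer cell markers were higher in 6 of 11 (median 1.10, with Cd5l at 2.44) and neutrophil markers in 5 of 6 (median 1.27, with S100a9 at 2.92 and S100a8 at 2.68). Interferon response genes were higher in 13 of 22 (median 1.08, with Oas1a at 1.89, Usp18 at 1.88 and Cxcl10 at 1.72). Inflammatory mediators were higher in 5 of 18 with 13 within 2-fold (median 0.73): the adhesion molecule Vcam1 stood at 3.09, the monocyte attractant Ccl2 at 2.30 and Icam1 at 1.68. Acute phase genes had 11 higher and 1 lower of 21 (median 1.40, with Mt2 at 3.51 and Il1rn at 2.44).

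Fibrosis and extracellular matrix genes were higher in 18 of 23 with none lower (median 1.37): Col3a1 stood at 3.06 (79.5 against 5.57 FPKM), Col1a1 at 2.81 (14.6 against 0.516) and Ccn2, a matricellular growth factor, at 2.18. Stellate cell markers followed with 7 of 17 (median 0.73, with Vim at 2.06). Cell cycle genes were higher in 14 of 17 (median 1.45, with Mcm6 at 2.59 and Mcm5 at 2.36). The circadian clock list had 7 higher and 1 lower of 13 (median 1.12, with Per2 at 1.46 and Dbp at 3.36, 38.1 against 1.60 FPKM). Immediate early genes had 4 higher and 1 lower of 12 (median 0.71, with Btg2 at 1.92 and Jun at 1.76), heat shock 1 of 10 (median 0.79, with Hspa1b at 1.12), and cholangiocyte markers 2 of 8 (median 0.82, with Krt23 at 2.29). Lists near the matched genes included endothelial markers (-0.01), gluconeogenesis (-0.06) and cytosolic ribosomal proteins (0.13).

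Of 38 lists tested in liver, 19 lay in the highest and 10 in the lowest 2.5% of random lists, against 1.9 by chance, and 20 of these 29 kept their place under every alternative tried. The female-biased list ended on the other side, at -0.16, with no filter on low values, the clock list stood at 0.13 and cholangiocyte markers at 0.23 there, both inside the random lists. With the mean over members hepatocyte identity (-0.57), complement (-0.45), mitochondrial DNA (-0.66) and erythroid markers (-1.03) left the outer range. NRF2 targets left it with a pseudocount of 5 FPKM (0.33), and bile acid genes without genes held mostly by 1 library (-0.35). Of 12866 genes, 2633 were at least 2-fold higher and 416 lower as deposited (86.4% higher). Relative to the median gene these were 928 and 985 (48.5%), after median-of-ratios scaling 1309 and 868 (60.1%), and with libraries scaled to the same sum 5137 and 264 (95.1%). Over the alternatives and the ratios relative to the median gene, 761 to 5137 were higher and 220 to 985 lower.

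**Figure D1:**
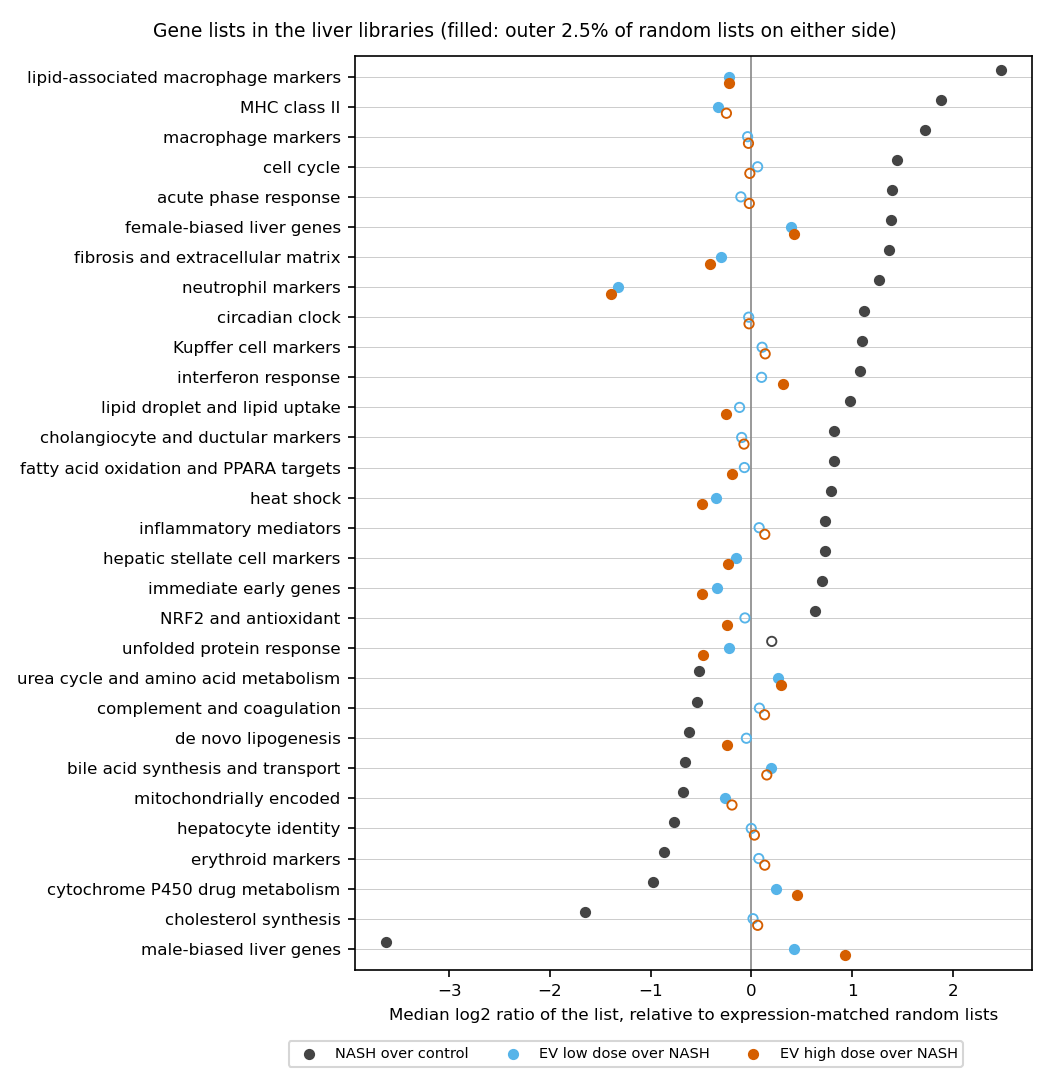
Median log2 ratio of each liver list relative to random lists of matched expression, for NASH over control (black), EV low dose over NASH (blue) and EV high dose over NASH (orange), with filled points in the outer 2.5% on either side. Male-biased liver genes lay at -3.63 in NASH and at 0.43 and 0.93 in the EV libraries, and neutrophil markers at 1.27, -1.32 and -1.39.

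With the low EV dose the liver held less RNA for neutrophil calprotectin and for matrix and stress genes than the NASH liver, and more for several male-biased genes and for Thrsp. S100a8, a calprotectin subunit of neutrophils and monocytes, was at 6.89 FPKM against 26.7 in NASH (log2 -1.68, gene ID 20201, chromosome 3, 90669071 to 90670034), and S100a9, its partner, at 10.2 against 33.2 (log2 -1.47). Camp, a neutrophil granule peptide, was listed at 0 against 3.29, and Chil3, a chitinase-like protein of myeloid cells, was at 2.49 against 7.92 (log2 -1.22). Thrsp was at 57.2 FPKM against 13.2 in NASH and 60.6 in control (log2 2.17, gene ID 21835, chromosome 7, 97412933 to 97417550).

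Other genes lower in this library were the histone H2bc6 (log2 -2.00), the MHC class II chaperone H2-DMa (log2 -1.15), the stress-induced pseudokinase Trib3 (log2 -1.13), Enho (log2 -1.07) and the aminopeptidase Enpep (log2 -1.04). Higher were Cyp2c39 (17.5 against 2.01 FPKM, log2 2.76), Mup14 (log2 1.62), Ugt1a9 (log2 1.60) and the ribosomal pseudogene Rps7-ps3 (log2 2.36), whose assignment apart from its parent gene is uncertain.

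Neutrophil markers had 4 of 6 lower (median -1.32). Fibrosis and matrix genes were lower as a list (median -0.30) with 23 of 23 members within 2-fold. Ccn2 stood lowest (log2 -0.73), with Col1a1 next (7.95 against 14.6 FPKM, log2 -0.66). Stellate cell markers stood at -0.16 (17 of 17 within 2-fold, with Acta2 at -0.60). Smaller differences also lay below the matched genes in heat shock (-0.35, with Hspa1b at -0.65), immediate early genes (-0.34, with Egr1 at -0.94), and MHC class II (-0.34, with Cd74 at -0.37). So did mitochondrial DNA (-0.27, with ND4 at -0.62), the unfolded protein response (-0.23, with Asns at -0.61) and lipid-associated macrophage markers (-0.22, with Lgals3 at -0.27). Male-biased genes had 5 of 20 higher and none lower (median 0.43, with Slco1a1 at 1.49). Cyp2c54, a member of the P450 list, stood at 1.41. Female-biased genes (0.40), urea cycle genes (0.26, with Hal at 0.92), P450 genes (0.25, with Cyp2c50 at 0.88) and bile acid genes (0.19, with Slc27a5 at 0.70) were also above the matched genes. Lists that named an aim and stayed within the random lists were inflammatory mediators (0.08, 18 of 18 within 2-fold, Cxcl9 at -0.62), fatty acid oxidation (-0.07, 25 of 25, Fgf21 at -0.79) and lipogenesis (-0.05, 16 of 17, Me1 at -0.38 against Thrsp).

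Of 12866 genes 40 were 2-fold higher and 49 lower (44.9% higher, 62.8% after median-of-ratios and 29.8% after same-sum scaling), and 57 and 29 relative to the median gene. Over the alternatives that compare with NASH these counts ran from 18 to 112 and from 5 to 231. Against control they were 1744 and 343. Of 38 lists 5 were called high and 9 low, 12 of these 14 under every alternative. MHC class II left the outer range with no filter (-0.18) and stellate cell markers with a filter at 5 FPKM (-0.15).

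The high EV dose gave the same direction for male-biased genes and calprotectin in liver, at larger size for the former. Slco1a1 was at 22.3 FPKM against 1.86 in NASH and 158 in control (log2 3.16, gene ID 28248, chromosome 6, 141907281 to 141946962), and Mup14 at 164 against 22.3 and 2311 (log2 2.96). S100a9 was at 9.46 against 33.2 FPKM (log2 -1.58) and S100a8 at 8.65 against 26.7 (log2 -1.39). Nupr1, a chromatin protein induced by stress, was at 11.8 against 40.4 (log2 -1.56) and Fgf21 at 10.9 against 32.1 (log2 -1.34). Hamp2, a copy of the gene for the iron hormone hepcidin, was at 4.50 against 359 FPKM (log2 -5.90, gene ID 66438, chromosome 7, 30922372 to 30924181), while Hamp was at 600.36 against 418, and assignment between the 2 copies is uncertain.

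Male-biased genes had 12 of 20 higher and none lower (median 0.93, with Mup7 at 2.55). P450 genes had 4 of 20 higher (median 0.45, with Cyp2c54 at 2.30 and Cyp2c50 at 1.45) and female-biased genes 1 of 10 (median 0.42, with Acot3 at 1.31). Interferon response genes were higher as a list (0.31) with 22 of 22 within 2-fold, led by Ifit1 (log2 0.96) and Ifit3 (28.3 against 16.7 FPKM, log2 0.87), and urea cycle genes stood at 0.29 (1 of 21 higher, with Hal at 1.02). Neutrophil markers had 4 of 6 lower (median -1.39). Matrix genes had 1 of 23 lower and 22 within 2-fold (median -0.41): Col1a1 stood at -1.04, Ccn2 at -0.95 and Tgfb1, the main fibrogenic cytokine, at -0.66 (3.15 against 6.18 FPKM). Stellate cell markers had 1 of 17 lower (-0.23, with Acta2 at -0.81).

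Stress genes were lower again: the unfolded protein response (-0.48, 1 of 16 lower, with Trib3 at -1.33, Asns at -0.81 and Ddit3 at -0.62) and heat shock (-0.49, 1 of 10, with Hspa1b at -1.05). Immediate early genes (-0.50, 12 of 12 within 2-fold, with Egr1 at -0.92 and Fos at -0.78) and NRF2 targets (-0.24, 1 of 17, with Osgin1 at -1.11) followed. Lipid droplet genes (-0.25, with Cidec at -0.64 and Plin4 at -0.62) and lipogenesis (-0.24, 1 of 17 higher, Thrsp at 1.78, against Me1 at -0.56 and Fasn at -0.42) lay below the matched genes, and so did fatty acid oxidation (-0.20, 1 of 25 lower, Fgf21, with Cyp4a31 at -0.59 and Pdk4 at -0.51). Lipid-associated macrophage markers stood at -0.23, where Cd63 was lower (log2 -0.66) and Mmp12 higher (46.9 against 30.1 FPKM, log2 0.76). Inflammatory mediators stayed within the random lists (0.13, 18 of 18 within 2-fold), with Cxcl1 at 0.69 and Cxcl9 at -0.47.

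Of 12866 genes 71 were 2-fold higher and 93 lower (43.3% higher, 66.4% after median-of-ratios and 23.55% after same-sum scaling), and 105 and 48 relative to the median gene. Over the alternatives that compare with NASH these counts ran from 41 to 160 and from 14 to 439. Against control they were 1737 and 330. Of 38 lists 5 were called high and 11 low, 10 of 16 under every alternative. Lipogenesis (-0.14), lipid-associated macrophage markers (-0.16) and urea cycle genes (0.16) left the outer range with the mean over members, lipid droplet genes (-0.06) with no filter, and NRF2 targets (-0.17) and stellate cell markers (-0.15) with a filter at 5 FPKM.

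**Figure D2:**
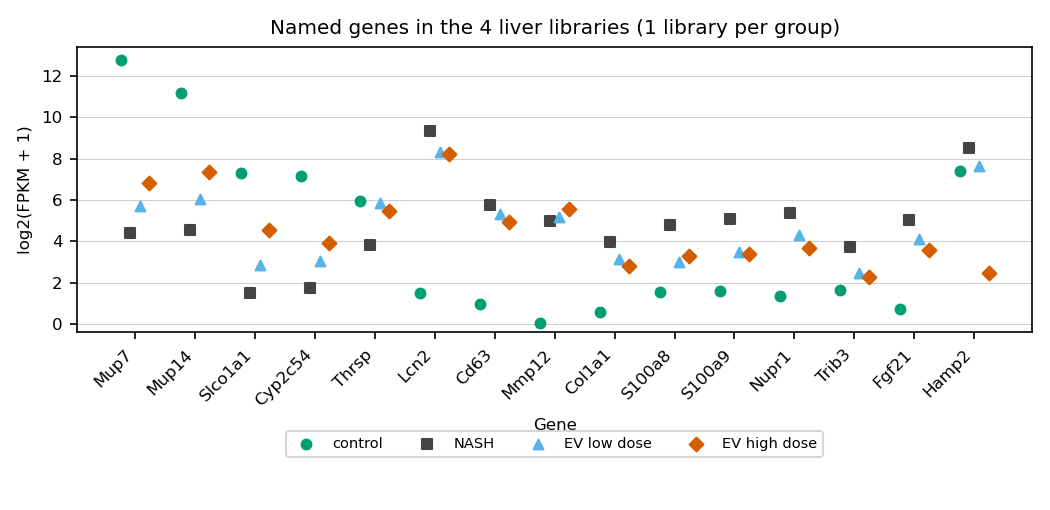
Log2(FPKM + 1) of 15 genes in the 4 liver libraries (green control, black NASH, blue EV low dose, orange EV high dose). Slco1a1 ran from 158 FPKM in control to 1.86 in NASH, 6.29 at the low and 22.3 at the high dose, and Hamp2 was at 4.50 in the high dose library against 169 in control and 359 in NASH.

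Between the doses, liver male-biased genes were higher at the high dose (median 0.64, 7 of 20 higher, none lower, with Slco1a1 at 1.67, and Mup14 outside the list at 1.34). So were interferon response genes (0.23, with Ifit3 at 0.73), B and plasma cell markers (0.32, with Igkc at 0.78) and acute phase genes (0.14, with Saa1 at 0.72, 206 against 125 FPKM). The unfolded protein response (-0.22), heat shock (-0.18), immediate early genes (-0.11), matrix (-0.09) and lipogenesis (-0.09) were lower at the high dose. Psma3, a proteasome subunit, was at 122 FPKM against 52.8 (log2 1.19), and Hamp2 (log2 -5.21), Cyp2c39 (log2 -2.82) and Bcl6, a transcriptional repressor (1.70 against 5.85 FPKM, log2 -1.35), were lower. The 2 EV livers were closer to each other (r 0.993) than either was to NASH (r 0.987 and 0.980), and 39 genes were 2-fold higher and 21 lower at the high dose. Of 38 lists 7 were called high and 7 low between the doses. Against NASH these were 5 and 9 at the low and 5 and 11 at the high dose. The number of list calls alone thus does not mark a difference between EV and NASH.

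Both EV livers lay slightly on the control side of NASH, and relative to the median gene this was mainly at genes lower than in control. Across the 3049 genes that differed 2-fold between NASH and control, the median share of that difference left was 0.82 at the low dose (95% interval over genes 0.81 to 0.83) and 0.78 at the high dose (0.77 to 0.80). This share uses the NASH library on both sides and stood at 0.48 in simulated libraries with no group differences. Noise alone picks the genes there and fixes the share near that value, so it is no baseline for genes that differ between groups. On genes chosen from the other EV library against control, the median log2 step toward control as deposited was -0.14 at the low dose (2067 genes, 71.8% toward control, and -0.07 after median-of-ratios or -0.25 after same-sum scaling) and -0.20 at the high dose (2087 genes, 73.6%). As deposited, genes higher than in control stood at -0.15 (73.6% toward control) at the low and -0.19 (73.3%) at the high dose. Genes lower than in control stood at -0.12 (62.4%) and -0.30 (75.2%). Part of the step as deposited was the shift of the whole library. Relative to the median gene the step was -0.08 at the low and -0.17 at the high dose: genes higher than in control stood at 0.03 and -0.01, and genes lower than in control at -0.20 (73.9% of 769 toward control) and -0.33 (78.0% of 847). These steps were not matched for expression. In the highest of 20 expression bins the median as deposited was 0.08 at the low and 0.13 at the high dose against NASH. In NASH over control it was -0.06. These were the highest bin medians of the EV ratios and the lowest of NASH over control. Part of the step at genes lower than in control may thus follow a trend with expression. As deposited, genes 2-fold higher than NASH at both doses numbered 26, with 7.16 in simulated libraries that share NASH and 0.221 for independent lists, and 24 were lower, with 7.02 and 0.354. Over the alternatives these counts ran from 7 to 60 higher and from 5 to 126 lower. The covariance of the 2 EV ratios was 0.08 (simulated 0.02), and that of each EV ratio with the NASH ratio -0.11 and -0.15 (simulated -0.02). The simulated values already include the sharing of a NASH library, but their noise came from the EV libraries. Part of the excess may thus come from differences peculiar to the NASH library. The higher set held 17 Mup family genes with Slco1a1, Cyp2c54, Thrsp, Sult2a8 (14.6 FPKM in NASH, 39.0 and 77.8 with EVs) and Inmt, a methyltransferase (89.2, 237 and 304). The Mup genes are near-identical copies, while the simulation drew its noise gene by gene. Without genes held mostly by 1 library, the Mup genes among them, 7 were higher and 19 lower at both doses. The excess of higher genes thus rested mainly on the Mup family. The lower set held S100a8, S100a9, Camp, Ngp and Chil3 of myeloid cells with Trib3, Enpep and H2-DMa.

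The NASH colon library had high values for seminal vesicle and prostate genes, much less RNA for several mucosal defence proteins, and more for clock, adipocyte and bile acid genes than the control colon. Svs4 and Svs5, secretory proteins of the seminal vesicle, were at 6903 and 6210 FPKM and listed at 0 in the control colon (Svs4: gene ID 20941, chromosome 2, 164275956 to 164278307), and Pbsn, a prostate lipocalin, was at 863 and listed at 0. Mptx1, a mucosal pentraxin, was at 806 FPKM against 12617 in control (log2 -3.97, gene ID 66289, chromosome 1, 174330518 to 174332877), Ang4, an antimicrobial ribonuclease, at 184 against 2004 (log2 -3.44), and Itln1, a lectin for microbial glycans, at 3.55 against 72.5 (log2 -4.01). Clca1, which processes mucus, was at 648 against 3915 (log2 -2.59) and Retnlb, a resistin-like goblet cell protein, at 149 against 1386 (log2 -3.21).

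The lists that hold these mucosal genes lay near the matched genes. Goblet cell and mucin genes had 4 lower, 2 higher and 14 within 2-fold of 20 (median -0.07, within the random lists): Clca1, Spink4 (log2 -2.10) and Fcgbp (log2 -1.73) were lower, Creb3l1 higher (log2 1.39), and Muc2, the main gel mucin, was at 1760 against 1519 FPKM. Antimicrobial and epithelial defence genes had 9 lower and 5 higher of 23 (median -0.12, within the random lists, but -0.45 and in the outer range with the mean over members). Reg3b, a lectin that kills bacteria, lay in the opposite direction to Ang4, at 684 against 42.1 FPKM. Tight junction and barrier genes were slightly higher (0.22, 1 lower, 19 within 2-fold of 20), with Cldn2, a pore-forming claudin, at 0.80 and Cldn8, a sealing claudin, at -1.10. Inflammatory mediators stayed within the random lists (-0.15, 14 of 14 within 2-fold, with Tlr2 at 0.99).

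The clock list had the highest median, 1.999, with 10 higher and 1 lower of 14: Dbp at 46.1 against 1.67 FPKM (log2 4.14, chromosome 7, 45705100 to 45710203), Tef at 3.18 and Per2 at 2.53. Adipocyte markers were higher in 8 of 10 (median 1.56, with Cidec at 2.12, Adipoq at 1.72 and Cfd at 1.75, 95.6 against 27.7 FPKM), and lipid droplet genes in 6 of 15 (median 0.90). Intestinal bile acid genes had 5 higher and 1 lower of 11 (median 0.90): the ileal uptake carrier Slc10a2 stood at 3.06, the export subunit Slc51a at 3.61, the binding protein Fabp6 at 2.62 and Cyp2c55 at -2.25. Small intestine markers, which share some of these genes, were higher in 5 of 13 (median 0.75). Fatty acid oxidation had 5 of 21 higher (median 0.35, with Acaa1b at 1.75, Ppara at 1.57 and Pdk4 at 1.51), while lipogenesis stayed within the random lists (0.07, 2 of 17 higher, Scd1 at 2.14 and Dgat2 at 1.29). Mitochondrial DNA transcripts (0.54, with ND4 at 1.13), immediate early genes (0.37), enteric neuron (0.26), stem cell (0.26, with Sox9 at 0.92) and colonocyte markers (0.24, Aqp4 lower, log2 -1.32) lay above the matched genes with few members beyond 2-fold.

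Pancreatic acinar genes were lower in 12 of 13 (median -2.60, with Amy2a5 at -3.61) from low control values of 295 FPKM in sum. Cell cycle genes had 9 of 20 lower and none higher (median -0.96, with Cdk1 at -1.29, Ccnb1 at -1.31 and Birc5 at -1.42, 5.94 against 17.6 FPKM), and replication-dependent histones 8 of 15 (median -0.86, with H2bc3 at -1.51). Cholesterol synthesis (-0.46), matrix (-0.43, 2 of 23 lower, with Col5a2 at -1.11 and Col3a1 at -1.42, 54.8 against 148 FPKM), and macrophage markers (-0.26, with C1qa at -0.43) were lower as lists. So were B and plasma cell markers (-0.25, with Igha at -0.92, 851 against 1608 FPKM), the unfolded protein response (-0.21) and nuclear oxidative phosphorylation genes (-0.14). The pseudogene Rps18-ps6 (log2 -6.13) was among the lowest genes, with an uncertain assignment apart from Rps18 (log2 -0.04).

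Of 38 lists tested in colon, 12 lay in the highest and 9 in the lowest 2.5%, and 14 of these 21 kept their place under every alternative. Tight junctions (0.15), colonocyte markers (0.13) and macrophage markers (-0.22) left it with the mean over members. So did neuron markers (0.26), nuclear oxidative phosphorylation (-0.12) and the unfolded protein response (-0.12), and B and plasma cell markers with a pseudocount of 5 FPKM (-0.09). Of 15245 genes 371 were 2-fold higher and 300 lower (55.3% higher, or 67.5% with libraries scaled to the same sum), with 122 to 847 and 144 to 521 over the alternatives.

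**Figure D3:**
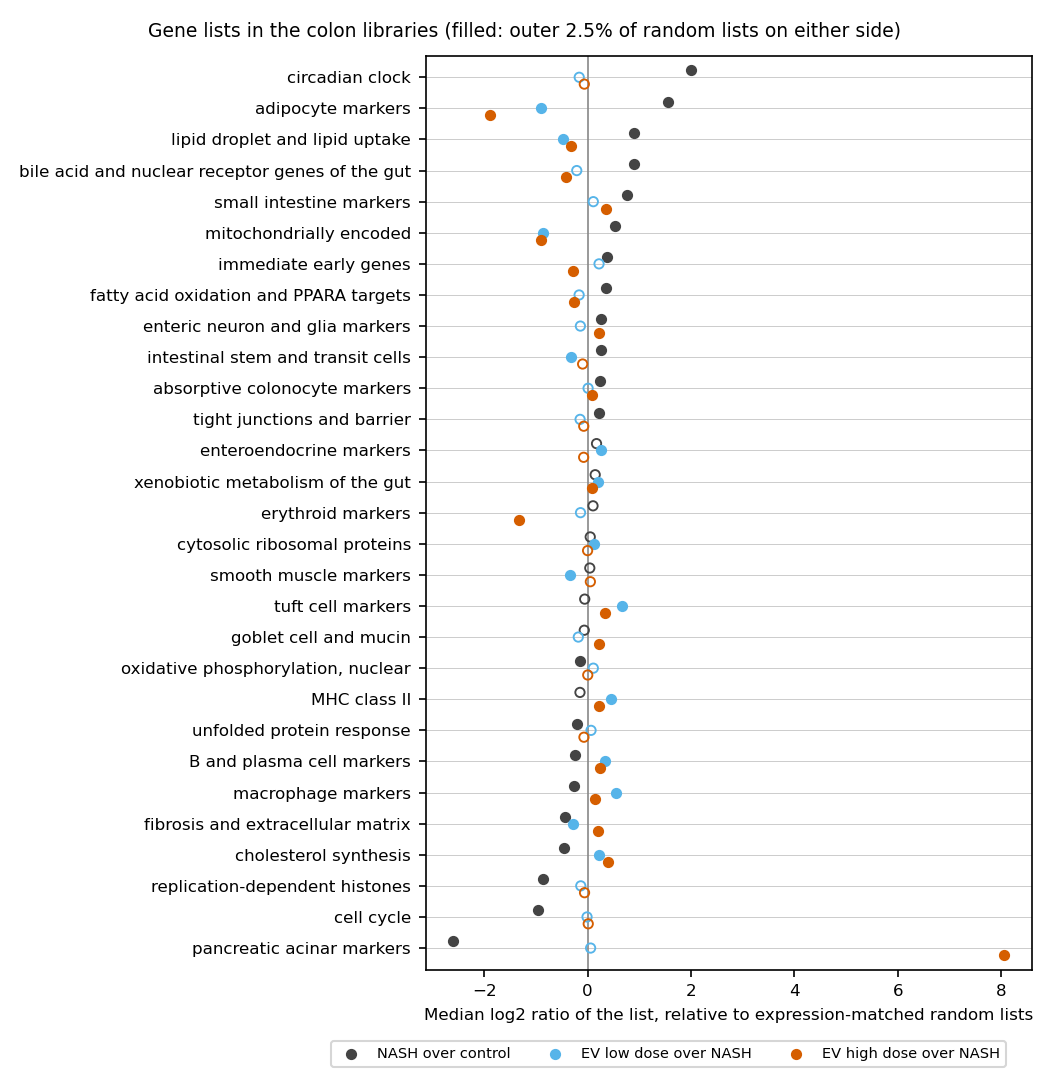
Median log2 ratio of each colon list relative to random lists of matched expression, for NASH over control (black), EV low dose over NASH (blue) and EV high dose over NASH (orange), with filled points in the outer 2.5% on either side. Adipocyte markers lay at 1.56, -0.90 and -1.88, and pancreatic acinar markers at 8.06 in the high dose library.

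With the low EV dose 5 mucosal genes picked for low values in the NASH colon were higher than in NASH, while the medians of the lists that hold them stayed near the matched genes. Svs4, Svs5 and Pbsn were listed at 0. Mptx1 was at 7702 FPKM against 806 in NASH (log2 3.25), Ang4 at 1753 against 184 (log2 3.25), Itln1 at 38.5 against 3.55 (log2 3.12), Clca1 at 3022 against 648 (log2 2.22) and Retnlb at 658 against 149 (log2 2.13). Reg3b was at 107 FPKM against 684, and Scd1, a desaturase of fatty acid synthesis, at 30.5 against 77.2 (log2 -1.31).

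Goblet cell genes had 5 higher, 1 lower and 14 within 2-fold of 20, yet a median below that of matched genes (-0.18, within the random lists). With a filter at 5 FPKM this list stood at -0.21, in the outer range. Clca1, Spink4 (log2 1.38) and Zg16 (log2 1.36) were higher, Creb3l1 was lower (log2 -1.79) and Muc2 was at 1097 against 1760 FPKM. Antimicrobial and epithelial defence genes had 5 higher and 5 lower of 23 (0.02, but 0.20 and in the outer range with the mean over members). Tuft cell markers (0.66, 8 of 8 within 2-fold, with Ltc4s at 0.82 and Alox5ap at 0.70) and macrophage markers (0.55, 14 of 14, with Adgre1 at 0.76 and C1qa at 0.81, 44.6 against 24.995 FPKM) were higher as lists, and so was MHC class II (0.46, 9 of 9, with H2-Ab1 at 0.84 and Cd74 at 0.70). B and plasma cell markers had 5 of 14 higher (0.34, with Igha at 1.23, 1998 against 851 FPKM, and Jchain, which joins secreted antibody, at 1.31). Enteroendocrine markers (0.26, with Insl5 at 0.86), cholesterol synthesis (0.21, with Fdps at 0.85), xenobiotic genes (0.20, with Cyp2c55 at 1.44) and ribosomal proteins (0.12) followed.

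Adipocyte markers were lower in 4 of 10 (median -0.90, with Car3 at -1.23, Fabp4 at -1.02 and Cfd at -1.002). Lipid droplet genes were lower in 2 of 15 (-0.47, with Cidea at -1.68) and mitochondrial DNA transcripts in 3 of 13 (-0.86, with ND4 at -1.72, 26.8 against 90.2 FPKM). Smooth muscle (-0.34, with Mylk at -0.27), stem cell (-0.33, with Sox9 at -1.04) and matrix genes (-0.29, 23 of 23 within 2-fold, with Bgn at -0.95 and Col1a1 at -0.78) were lower as lists. Within the random lists were tight junctions (-0.15, 20 of 20 within 2-fold, with Cldn2 at -0.42), inflammatory mediators (0.13, 14 of 14, with Ccl2 at 0.74 and Ccl5 at -0.71), lipogenesis (-0.19, 1 of 17 lower, Scd1) and fatty acid oxidation (-0.16, 1 of 21 higher). Of 15245 genes 138 were 2-fold higher and 297 lower (31.7% higher, or 19.9% with libraries scaled to the same sum), with 50 to 302 and 80 to 773 over the alternatives, and 9 of the 14 called lists, 8 high and 6 low, kept their place under every alternative. The enteroendocrine (0.19), cholesterol (0.13), ribosomal (0.16), stem cell (-0.25) and xenobiotic lists (0.20) left it with the mean over members.

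With the high EV dose the colon library had high values for genes of pancreatic enzymes and low values for adipocyte markers. Whether pancreas or fat beside the colon was taken along at dissection was not tested, so these values may not describe the colon wall. Ctrb1, a chymotrypsinogen, was at 530 FPKM against 0.190 in NASH (log2 8.80, gene ID 66473, chromosome 8, 111686510 to 111691010), Prss2, a trypsinogen, at 499.9 against 0.265, and Pnlip, pancreatic lipase, at 417 and listed at 0 in NASH. Mptx1 was at 6769 FPKM, Ang4 at 1154, Itln1 at 146 and Clca1 at 2807, each several-fold above NASH as at the low dose, and Retnlb at 371 (log2 1.31). Reg3b was at 8.70 FPKM against 684, and Cfd, the adipocyte protease adipsin, at 12.4 against 95.6 (log2 -2.85).

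Pancreatic acinar markers were higher in 13 of 13 (median 8.06) and made up 1.14% of the protein-coding FPKM, against 0.0799% in the control colon and 0.0272% in the NASH colon. Goblet cell genes were higher as a list (0.23, 3 of 20 higher, none lower, with Clca1 at 2.11, Fcgbp at 1.47 and Spink4 at 1.29), with Muc2 at 1854 FPKM. Antimicrobial and epithelial defence genes had 6 higher and 6 lower of 23 (-0.01, but 0.24 and in the outer range with the mean over members). Cholesterol synthesis (0.40, with Fdft1 at 0.80), small intestine markers (0.35, 2 higher and 2 lower of 13, with Apoa4 at 2.26 against Fabp6 at -2.24) and tuft cell markers (0.33) were above the matched genes. So were B and plasma cell (0.24, with Iglc1 at 2.06 and Igha at 0.81), MHC class II (0.23) and neuron markers (0.21, with Nos1 at 0.64). Matrix (0.19, 23 of 23 within 2-fold, with Col3a1 at 0.74), macrophage (0.15), xenobiotic (0.09) and colonocyte markers (0.08, with Slc26a3 at 0.80, 361 against 207 FPKM) were above the matched genes.

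Adipocyte markers were lower in 7 of 10 (median -1.88, with Car3 at -2.49 and Adipoq at -2.32) and erythroid markers in 4 of 5 (-1.33, with Hbb-bs at -1.20, 61.3 against 142 FPKM). Mitochondrial DNA transcripts were lower in 3 of 13 (-0.90, with ND2 at -1.31) and bile acid genes in 3 of 11 (-0.42, with Slc51a at -2.10). Lipid droplet genes (-0.33, 4 of 15 lower, with Cidea at -1.82 and Cd36 at -1.63), immediate early genes (-0.29, with Zfp36 at -0.67) and fatty acid oxidation (-0.26, 4 of 21 lower, with Angptl4 at -1.40 and Pdk4 at -1.24) were lower too. Tight junctions (-0.08, 20 of 20 within 2-fold, with Cldn2 at -0.56), inflammatory mediators (0.03, 14 of 14, with Tlr2 at -0.73) and lipogenesis (-0.07, 2 of 17 lower, with Scd1 at -2.13) stayed within the random lists. Of 15245 genes 167 were 2-fold higher and 218 lower, with 67 to 300 and 75 to 449 over the alternatives, and 11 of the 19 called lists, 12 high and 7 low, kept their place under every alternative. Small intestine markers stood at -0.00269 with no filter and xenobiotic genes at -0.02 with the mean over members. With the mean MHC class II (0.20), colonocyte (0.05), neuron (0.13), matrix (0.16), macrophage (0.19) and tuft cell markers (0.26) also left the outer range.

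**Figure D4:**
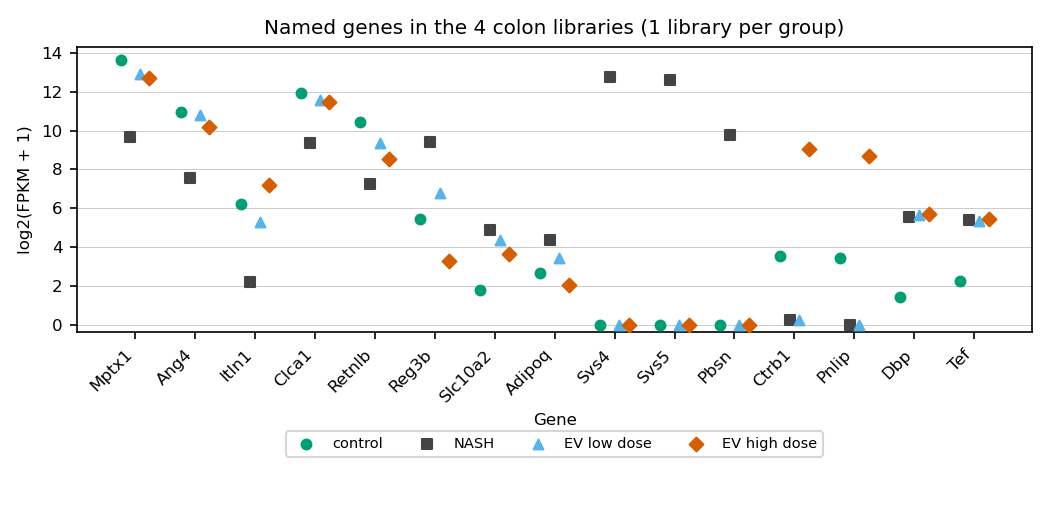
Log2(FPKM + 1) of selected genes in the 4 colon libraries (green control, black NASH, blue EV low dose, orange EV high dose). Mptx1 was at 12617, 806, 7702 and 6769 FPKM in that order, and Ctrb1 was at 530 in the high dose library.

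Between the doses in colon, apart from the pancreatic genes (median 8.06, 13 of 13 higher at the high dose), matrix genes were higher at the high dose (0.47, 1 of 23 higher, with Col1a1 at 1.08, 7.81 against 3.16 FPKM). So were smooth muscle (0.40), neuron (0.32), cholesterol (0.22), stem cell (0.20) and goblet cell genes (0.20, with Muc3 at 0.80 and Muc2 at 0.76). Lower at the high dose were erythroid (-1.10), adipocyte (-0.80) and immediate early genes (-0.58, with Fos at -0.82), and macrophage markers (-0.38). Bile acid genes (-0.32), T and NK cell markers (-0.31, with Gzma at -1.13), MHC class II (-0.30), fatty acid oxidation (-0.27) and heat shock (-0.20, with Hspa1a at -1.42) were lower too. Reg3b stood at -3.48, Fabp6 at -2.17 and the gut peptide Nts at -1.51. The 2 EV colons had r 0.969, with 133 genes 2-fold higher and 104 lower at the high dose. Of 38 lists 7 were called high and 12 low between the doses. Against NASH these were 8 and 6 at the low and 12 and 7 at the high dose. As in liver, the number of list calls alone does not mark a difference between EV and NASH.

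In colon the step of the EV libraries toward control was small on genes chosen without NASH. That choice leaves out genes that the other EV library held within 2-fold of control. As whole libraries the EV colons had a higher r with control (0.974 and 0.969) than with NASH (0.956 and 0.949). A robust spread of the log2 ratios, the scaled median absolute deviation, split the doses. At the low dose it was 0.24 to control and 0.36 to NASH. At the high dose it was 0.26 to control and 0.21 to NASH, so by that measure the high dose colon was closer to NASH. NASH and control had r 0.946. Genes 2-fold apart from control numbered 441 at the low dose, 396 at the high dose and 671 in NASH. The accessory gland genes add to the count in NASH and may lower each r with NASH. The median share of the NASH difference left was 0.53 at the low dose (0.49 to 0.59, 671 genes) and 0.55 at the high dose (0.50 to 0.60). It stood at 0.49 in simulated libraries with no group differences, where noise alone picks the genes. That value is no baseline for genes that differ between groups, so the share cannot tell an EV effect from noise. The share left was lower for genes higher in NASH (0.36 and 0.40) than for genes lower in NASH (0.81 and 0.71). On genes chosen from the other EV library against control, the step was -0.02 (-0.08 to 0.00, 50.8% of 396 genes toward control, and -0.08 with a pseudocount of 0.1 FPKM) and -0.06 (-0.12 to -0.02, 56.01% of 441), so genes chosen without NASH hardly stood closer to control. Genes 2-fold lower than NASH at both doses numbered 122 (simulated 42.9, independent 4.25) and 60 were higher (simulated 42.5, independent 1.51). Over the alternatives these counts ran from 49 to 267 lower and from 29 to 133 higher. The covariance of the 2 EV ratios was 0.19 (simulated 0.10), and that of each with the NASH ratio -0.22 and -0.21 (simulated -0.10). As in liver, the simulated values include the sharing of a NASH library but not what is peculiar to the real one, such as the accessory gland genes. Part of the excess may come from these. The lower set held the accessory gland genes, Reg3b, Reg3g, Nos2, Duox2, Saa3, Mmp7 (49.3 FPKM in NASH, 1.22 and 0.549 with EVs), and Ceacam10. It also held the fat genes Cfd, Fabp4, Scd1, Cidea and Ucp1, the uncoupling protein of brown fat (15.2 FPKM in NASH, listed at 0 in the other 3 colons). The higher set held Mptx1, Ang4, Itln1, Clca1, Retnlb, Reg4 (54.8 FPKM in NASH, 166 and 169 with EVs), Spink4 and Fcgbp.

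Genes 2-fold apart in both tissues in NASH were more than independent lists would give, in the same and in opposite directions. Of 11827 genes measured in both, 65 were 2-fold higher in the NASH library of both (33.9 for independent lists) and 26 lower (2.88), 84 lay in opposite directions (34.9), and the log2 ratios had r 0.15. Over the alternatives the shared counts ran from 20 to 182 higher (3.04 and 120.6 for independent lists) and from 12 to 43 lower (0.777 and 5.88). With libraries scaled to the same sum 138 were shared higher, against 114 for independent lists. The shared higher genes included the clock genes Dbp, Per1, Per2, Per3, Tef, Ciart and Nr1d2, the lipid genes Cd36, Cidec, Fabp4, Plin4, Pdk4, Angptl4 and Ppara, and the acute phase genes Saa3, Hp, Mt1 and Mt2. In colon adipocyte markers, Cidec and Fabp4 among them, were higher as a list (1.56), so fat tissue in the sample was not excluded as a source of the lipid genes. The shared lower genes included Arntl and several ribosomal pseudogenes, such as Rps18-ps6. These clock genes, Mt1, Arntl and Rps18-ps6 were also 2-fold apart between control and both EV libraries in both tissues, so they set the control libraries apart from the other 3 groups. Against NASH, 4 genes were higher and 4 lower in both tissues at the low dose (0.0418 and 0.440 for independent lists, r 0.41), and 5 and 5 at the high dose (0.0708 and 0.508, r 0.19). Liver and colon of a group may come from the same animals, and differences between animals would then recur in both tissues. Independent lists would in that case give too few, here and for NASH over control. An excess over them therefore does not show an effect of EVs or NASH. The higher genes at the low dose were the pseudogene Rps7-ps3 and the predicted genes Gm6937, Gm13841 and Gm8210. Of these Rps7-ps3, Gm13841 and Gm8210 were also 2-fold lower in NASH than in control, and at the high than at the low dose, in both tissues. Those at the high dose were Gm14038, Gm6937, Gm13736, Gm15484 and LOC115489078, also predicted. The lower genes were Enpep, Lmbr1, Phospho1 and Gm13394 at the low dose. At the high dose they were Enpep and the small RNA genes Snord14c, Snord14d, Mir6954 and Mir6955. With a pseudocount of 5 FPKM the counts were 3 and 1 at the low dose and 0 and 0 at the high dose. Enpep was lower at both doses in both tissues: 27.1 FPKM in NASH, 11.4 and 11.7 with EVs in liver, and 15.2, 5.18 and 5.98 in colon.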

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

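The lists below lay in the outer 2.5% of random lists in both tissues and on opposite sides of 0. Each difference between liver and colon is given as 2 values, and the difference itself was not tested, with 1 library per group. The tests in the paragraphs after them were chosen after the results were seen.

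Cell cycle genes were higher in the NASH liver than in its control (median 1.4482) and lower in the NASH colon than in its control (-0.9583). In liver Mcm6 stood at 2.59 and Mcm5 at 2.36, and in colon Birc5 stood at -1.42 and Cdk1 at -1.29. Fibrosis and extracellular matrix genes went the same 2 ways, at 1.3671 in liver and -0.4284 in colon: Col3a1 was at 79.5 against 5.57 FPKM in liver and at 54.8 against 148 in colon. Macrophage markers stood at 1.7205 in liver, where Cd68 was at 27.3 against 3.32 FPKM, and at -0.2643 in colon, where C1qa was at 24.995 against 33.9. Transcripts of mitochondrial DNA stood at -0.6827 in liver and 0.5385 in colon. With the mean over members the macrophage value in colon (-0.22) and the mitochondrial value in liver (-0.66) left the outer range, so these 2 contrasts rest on the median.

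Between the EV and NASH libraries, MHC class II genes were lower in liver at the low dose (-0.3358) and higher in colon (0.4608), with Cd74 at -0.37 and 0.70. Matrix genes at the high dose were lower in liver (-0.4076) and higher in colon (0.1948), with Col1a1 at -1.04 in liver and Col3a1 at 0.74 in colon. The MHC class II value in liver left the outer range with no filter on low values (-0.18), and the matrix value in colon with the mean over members (0.16).

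Seminal vesicle and prostate genes stood out in the NASH colon, with Svs4 at 6903 FPKM, Pbsn at 863 and Tgm4 at 385. Of the 16 genes of the list 15 reached 1 FPKM there and 1, Azgp1, in each other colon library, which may reflect RNA of these glands in the sample. For expression by colon cells in the disease, the higher of the 2 EV colons held 1.679 FPKM over the list and the control colon 1.9883, so the EV colons, from animals with the same disease, gave no sign of it. That test cannot separate a disease effect that the EVs removed from the absence of one.

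Mptx1, Ang4, Itln1, Clca1 and Retnlb were low in the NASH colon, with a median log2 ratio of -3.44. Dilution by RNA of another organ could lower all colon genes alike, but the 22 absorptive colonocyte markers had a median of 0.1083 (standard deviation 0.6138), which is evidence against it as the main cause. Fewer goblet cells would lower the other goblet cell genes, but those 19 genes had a median of -0.1693 (standard deviation 0.9012), and Muc2 was at 1760 FPKM against 1519. Some of the 19 were low as well, with Spink4 at 447 FPKM against 1917 in control and Fcgbp at 438 against 1462. Reg4, outside the list, was at 54.8 against 494. The members thus differ among themselves, and the median does not exclude fewer goblet cells. Another stretch of the colon remains possible: the anterior Hox genes, which mark position along the gut, had a median of 0.623 and the posterior ones -0.0523. An effect of NASH on these genes, which the EV libraries would then lack in part, was not tested and stays open.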

How the results depend on the processing

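The libraries had no replicates and the sequencing depth was unknown, so neither error nor the effect of depth on low genes could be measured, and the values below say how far the results rest on the processing. Names of comparisons are short here: NASH is NASH over control, EV low and EV high are each dose over NASH. No paired analysis was possible because each group held 1 library. No log2 ratio of a named gene beyond 2-fold turned its direction under another scaling, and another pseudocount cannot turn one. Over all ratios of named genes, within or beyond 2-fold, 550 kept their side of 2-fold after median-of-ratios scaling, 9 fell below and 9 rose above it. With a pseudocount of 5 FPKM 501 kept it and 67 fell below. A scaling factor per library moves a list and its random lists nearly alike, so few list calls could change under the 2 scalings, and those kept are not counted here. Of 228 list results, 226 kept their call with a pseudocount of 0.1 FPKM, 222 with a pseudocount of 5 FPKM and 215 with no filter. With the mean over members 190 kept it, and with a filter at 5 FPKM 191 of those still tested. Both EV livers stayed on the control side of NASH in each alternative under which their position was computed. Unless a reason is given, the cause was not tested.

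With the mean over members, which gives weight to the genes furthest apart, xenobiotic genes turned to -0.0226 in colon EV high. Lists that left the outer range in liver NASH were complement and coagulation (-0.45), erythroid markers (-1.03), hepatocyte identity (-0.57) and mitochondrial DNA (-0.66), and in liver EV high lipogenesis (-0.14), lipid-associated macrophages (-0.16) and urea cycle (0.16). In colon NASH these were colonocytes (0.13), neurons (0.26), macrophages (-0.22), nuclear oxidative phosphorylation (-0.12), tight junctions (0.15) and the unfolded protein response (-0.12). In colon EV low they were cholesterol synthesis (0.13), ribosomal proteins (0.16), enteroendocrine markers (0.19), stem cells (-0.25) and xenobiotic genes (0.20). In colon EV high they were MHC class II (0.20), colonocytes (0.0472), neurons (0.13), matrix (0.16), macrophages (0.19), small intestine (0.0639) and tuft cells (0.26). Lists that entered the outer range were the unfolded protein response in liver NASH (0.59), NRF2 (-0.14), acute phase (-0.20) and fatty acid oxidation (-0.12) in liver EV low, and MHC class II (-0.44) and bile acid genes (0.30) in liver EV high. In colon they were antimicrobial genes in NASH (-0.45), EV low (0.20) and EV high (0.24), small intestine in EV low (0.28), and lipogenesis (-0.26) and heat shock (-0.32) in EV high.

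With no filter, genes listed near 0 pull medians toward 0. Female-biased liver genes turned to -0.16 in liver NASH and small intestine markers to -0.00269 in colon EV high. Lists that left the outer range were cholangiocytes (0.23) and the clock (0.13) in liver NASH, MHC class II in liver EV low (-0.18), lipid droplets in liver EV high (-0.0636) and the unfolded protein response in colon NASH (-0.0899). Lists that entered it were bile acid genes (0.16) and complement (0.16) in liver EV high, inflammatory mediators in colon NASH (-0.11) and colon EV low (0.13), nuclear oxidative phosphorylation in colon EV low (0.17), and T and NK cells in colon EV high (-0.15).

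A filter at 5 FPKM leaves fewer genes to count. Genes 2-fold higher in liver NASH numbered 1695, lower in liver EV low 21 and EV high 55, and lower at both doses 14. In colon 235 were higher in NASH, 185 lower in EV low, 123 lower in EV high and 81 lower at both doses. Shared between tissues were 43 higher and 17 lower in NASH, 2 lower in EV low, and 1 higher and 3 lower in EV high. The share left was 0.84 in liver EV low and 0.61 in colon EV high. Lists that left the outer range were erythroid markers in liver NASH (-0.84), stellate cells in liver EV low (-0.15) and EV high (-0.15), NRF2 in liver EV high (-0.17) and ribosomal proteins in colon EV low (0.0742). Lists that entered it were bile acid genes in liver EV high (0.29), fatty acid oxidation (-0.26) and goblet cells (-0.21) in colon EV low, and enteroendocrine markers (-0.16) and interferon response (0.18) in colon EV high.

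A pseudocount of 0.1 FPKM widens the ratios of low genes by construction. Liver counts were 4249 higher in NASH, 112 higher and 231 lower in EV low, 160 higher and 439 lower in EV high, and 60 higher and 126 lower at both doses. Colon counts were 847 and 521 in NASH, 302 and 773 in EV low, 300 and 449 in EV high, and 133 and 267 at both doses. Shared between tissues were 182 and 43 in NASH, 14 and 46 in EV low, and 14 and 20 in EV high. The step toward control on genes chosen from the other EV library was -0.19 in liver EV low, -0.25 in liver EV high and -0.0835 in colon EV low, and the share left 0.49 in colon EV low. Neurons in colon NASH (0.33) left the outer range and interferon response in colon EV high (0.16) entered it.

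A pseudocount of 5 FPKM narrows the same ratios. Liver counts were 761 higher and 220 lower in NASH, 26 and 5 in EV low, 41 and 14 in EV high, and 5 lower at both doses. Colon counts were 122 and 144 in NASH, 63 and 80 in EV low, 82 and 75 in EV high, and 29 and 49 at both doses. Shared between tissues were 20 higher and 12 lower in NASH, 1 lower in EV low, and 0 and 0 in EV high. The share left was 0.86 and 0.81 in liver EV low and EV high and 0.60 in colon EV high, and the step -0.10 and -0.16 in liver. NRF2 in liver NASH (0.33), B and plasma cells in colon NASH (-0.0949) and macrophages in colon EV high (0.0674) left the outer range. Histones in liver NASH (0.34), MHC class II in liver EV high (-0.24) and NRF2 in colon NASH (0.14) entered it.

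Median-of-ratios scaling left more genes higher than lower in liver NASH (1309 and 868), unlike ratios relative to the median gene (928 and 985). After this scaling 29 were lower in EV low, 48 in EV high and 15 at both doses, and 42 were shared higher in NASH. The share left was 0.86 and 0.81 in liver EV low and EV high, and the step -0.0712 and -0.14. Erythroid markers in liver NASH (-0.86) left the outer range, and immediate early genes in colon EV low (0.22) and interferon response in colon EV high (0.12) entered it.

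With libraries scaled to the same sum, which small RNA genes dominate, liver NASH had 5137 higher and 264 lower, 99 were lower in EV low, 211 in EV high and 60 at both doses. In colon EV low 480 were lower, 138 were shared higher in NASH and 21 shared lower in EV low. The share left was 0.75 and 0.74 in liver EV low and EV high and 0.46 in colon EV low, and the step -0.25 and -0.28 in liver. B and plasma cells in liver NASH (-0.50) entered the outer range.

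Without predicted, small RNA and receptor segment genes there were fewer genes to count: 24 lower in liver EV low, 61 lower in liver EV high, 51 higher and 173 lower in colon EV low, and 68 and 130 in colon EV high. With protein-coding genes only, chosen after the data were seen, these were 24 lower in liver EV low, 191 lower in colon NASH, 50 and 185 in colon EV low, and 67 and 137 in colon EV high. Without genes held mostly by 1 library, also chosen after, 18 were higher in liver EV low, 47 in liver EV high and 7 at both doses, since Mup genes of the control liver were removed. In colon 67 were lower at both doses, since genes held mostly by the NASH colon, such as Svs4, Pbsn, Reg3b and Mmp7, were removed. There 15 were shared lower in NASH, the share left was 0.60 in colon EV high, bile acid genes in liver NASH (-0.35) left the outer range and immediate early genes in colon EV low (0.22) entered it. Relative to the median gene, chosen after the data were seen, the share left in liver EV low was 0.85 and the step -0.0752 in liver EV low and -0.17 in EV high. Against control in place of NASH, liver EV low had 1744 higher and 343 lower and EV high 1737 and 330, since the comparison then spans the NASH difference.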

Other observations

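Fat tissue genes beyond the white adipocyte markers also differed between colon libraries. Ucp1, the uncoupling protein of brown fat, was at 15.2 FPKM in the NASH colon and listed at 0 in the other 3, Cidea was higher in NASH than in either EV colon (log2 -1.68 and -1.82), and Cox8b, a respiratory subunit of brown fat, was at 8.26 FPKM in NASH and at 0.908, 1.38 and 1.49 in control, EV low and EV high dose. Among other genes outside the lists, Ceacam10 was at 310.2 FPKM in the NASH colon and at 59.2, 42.6 and 37.9 in the others, Mmp7, a protease that activates defensins, was at 49.3 against 0.291 in control, and Mptx2, a relative of Mptx1, was at 11.2, 0.859, 4.96 and 138 FPKM. Ceacam10 and Mmp7 peaked in the library where 15 seminal vesicle and prostate genes reached 1 FPKM, so gland RNA was not excluded as their source. These genes were chosen after their values were seen.

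In liver, Inmt, a methyltransferase, was at 773, 89.2, 237 and 304 FPKM in control, NASH, EV low and EV high dose, and Sult2a8, a sulfotransferase, at 373, 14.6, 39.0 and 77.8. The ribosomal pseudogene Rps7-ps3 was at 11.9, 2.65, 16.1 and 3.53 FPKM in the liver libraries in that order and at 36.3, 6.25, 44.3 and 8.33 in the colon libraries, so control and EV low dose were high in both tissues, and its assignment is uncertain. Protein-coding genes with over 75% of a tissue's summed FPKM in 1 library numbered 47 in the NASH colon (5.53% of its protein-coding FPKM), 34 in the EV high dose colon (1.39%) and 42 in the control liver (13.9%), and between 2 and 6 in the other libraries. In the EV high dose colon they included Ctrb1, Prss2 and Pnlip, which the pancreas makes.

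The control libraries stood apart from the other 3 groups in both tissues at the same genes, and the tests here were chosen after that was seen. Dbp was at 1.60 FPKM in the control liver against 38.1 in NASH and at 1.67 in the control colon against 46.1, while Arntl, a clock gene of the opposite phase, was at 5.53 against 0.816 and 18.4 against 2.47. A difference of 1 scaling factor per library could not make the opposite phases part by 2.6451 log2 units in liver and 3.1248 in colon. Another time of day at collection may be involved, but NASH itself might also shift the clock and the times are not in the labels. Of 10 clock genes 8 differed 2-fold in the direction of their phase in both tissues. These 8 were the clock genes already seen apart in control, so the count was fixed by that choice and decides nothing. The preset clock list in liver had 7 higher and 1 lower of 13 between NASH and control. Other alleles in the control animals are a possible explanation too: 13 genes were apart on the high side in both tissues, against 0.7264 for independent lists, 11 of them pseudogenes, and H2-Ea, which is not transcribed in some mouse haplotypes, was at 1.55 and 6.73 FPKM in the control libraries and listed at 0 in the other 6. Of the 11827 genes kept in both tissues 517 were pseudogenes. As deposited, the parents Rps18, Rps19 and Rpl21 stood between -0.04 and 0.39 in NASH over control, and their pseudogenes between -6.13 and -1.61. Glo1 was lower along with Glo1-ps, at -1.94 in liver and -0.46 in colon. If alleles differed, NASH over control and each step toward control would hold that difference too.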
